A study of Arabidopsis thaliana with 18 samples.

How the data were processed

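Total RNA of 18 samples of Arabidopsis thaliana Tsu-1 had been labelled with biotin and hybridised to Affymetrix ATH1 arrays, per the labels. The authors deposited one table of intensity values on a linear scale, one per probe set and array. MAS5 is the only tool in the submitters' processing notes, and its version is not given in the sources used here. All deposited values were above 0, and the trimmed mean of every array, with 2% taken off each end, was 100.01, so the values were used as deposited. The table held 22810 probe sets, 64 of them controls, with no detection calls.

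Gene names came from the platform annotation, with symbols updated through gene identifiers to the RefSeq table of assembly TAIR10.1. Of the 22746 probe sets other than controls, 13513 had 1 gene, 503 had several and were not named, and 8730 were not named here. No coordinates are given, since no genome build goes with the table. In place of symbols, loci were used where the tables gave none.

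Values were taken as log2. Controls and the lowest 30% of probe sets by mean log2 signal over all arrays (6824 probe sets) were left out, which left 15922 probe sets, 8743 of them with 1 gene. Low values of this kind of signal scatter widely on the log2 scale, so differences of dim probe sets are less precise. The treatments were compared with limma 3.58.1 in R 4.3.3 (linear model with treatment only, moderated by a mean-variance trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The same test was run within each replicate number, and an F-test was run on the interaction of treatment and number. Errors beside differences are the model's SE.

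Gene lists were tested with camera at its preset correlation of 0.01, which compares a list's members with all other probe sets. Beside it stand camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance. By fry, before adjustment, 1 of the 30 lists passed, the added jasmonate list. Lists needed at least 3 measured genes, multi-gene probe sets were not used, and the brightest probe set stood for a gene. The lists fixed before the data were examined (309 genes in 16 lists) were adjusted as 1 family of 6 testable lists. The annotation named a probe set for 41 of these genes, 13.3%. Therefore 25 lists were added from named genes before their values were seen, and the 24 testable ones were adjusted apart. This split into 2 families was settled after all 30 lists had been adjusted together and those p-values had been seen. The same 5 lists passed as 1 family, with adjusted p of 1.86e-06 for the SA-associated loci, 0.000928 for the added jasmonate list, 0.0207 for the fixed jasmonate list, 0.0207 for nuclear and 0.0435 for plastid photosynthesis. With an estimated correlation none of the 5 passed in its own family, with adjusted p of 0.714, 0.119, 0.115, 0.714 and 0.727. The added jasmonate, auxin, endoplasmic reticulum and photosynthesis lists share members with fixed lists, and the flavonoid list shares glycosyltransferases with the family list. The SA-associated loci were recalled from general knowledge and not taken from these arrays.

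The rule fixed beforehand named the 12 largest rises and 12 largest falls among called genes, PR1, PR2 and PR5, and up to 4 members per list with the smallest p-values. Its first part named no gene because none was called, and its second gave no value because no named probe set carried these genes. Other genes were chosen after their values were seen, as stated where they appear. For larger lists the text prints fewer than 4 members.

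Exact permutation tests were two-sided. They ran over all 48620 assignments of 18 arrays, or over the 8000 that keep 3 arrays of each replicate number in each treatment. Whether the replicate numbers pair arrays across treatments was checked before calls were compared, by correlating deviations of each number's mean from its treatment mean. This used the numbers of the labels. Same-numbered means correlated at 0.639, 0.683 and 0.58 for numbers 1, 2 and 3, and differently numbered means at -0.457 to -0.153. Deviations cancel out within a treatment, so the negative values follow partly from the positive ones. The numbers thus appear to pair the arrays, but the main tests kept treatment only. The pairing entered through the replicate block, an alternative, and through the permutations within numbers. In a model with treatment and number, 186 probe sets differed between numbers.

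The test was checked on simulated data before use, with 200 of 15922 probe sets changed by 0, 1, 2 or 3 log2 units between 9 and 9 arrays in 10 random splits. On residuals of the arrays it recovered a median of 0, 122, 191 and 198.5 changed probe sets, and the highest number of unchanged probe sets called was 8. On independent noise with no structure between arrays, it recovered 129, 192 and 199 for changes of 1, 2 and 3 units. The highest number of unchanged probe sets called there was 16.

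Alternatives chosen before the data were examined were no filter, a 50% filter, adding the 10th percentile, a floor at the 20th percentile, quantile normalization, median scaling, the replicate block, moderation without trend, robust moderation, array weights, an estimated correlation, the median of a gene's probe sets, and leaving out each replicate number and each array. Added later were 1 to 5 components of the residuals as covariates, a rank-sum test, a test of spread, permutation of list means, and leaving out the 2 arrays that correlate least with the others.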

Results

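The data were 18 Affymetrix ATH1 arrays hybridised with biotin-labelled total RNA from Arabidopsis thaliana of the accession Tsu-1. Of these, 9 arrays came from plants treated with 0.3 mM salicylic acid (SA), the plant hormone of defence against biotrophic pathogens, in 0.02% silwet. The other 9 came from plants given 0.02% silwet alone, a surfactant that helps a spray to spread and is the control here. Each treatment used the replicate numbers 1, 2 and 3, and each number stood on 3 arrays per treatment. The labels did not say what separated those 3 arrays. They gave no tissue, age or time after treatment. Arrays are named by the array numbers in their titles, 91 to 99 for silwet and 100 to 108 for SA. Nothing in the labels says that arrays of one treatment came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

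The table held one signal per probe set on each array, and the number of arrays limits the precision. The median signal of the probe sets other than controls ran from 26.01 on SA array 100 to 35.9 on SA array 106. Correlations of log2 signal between arrays ranged from 0.808 to 0.977 for the 72 pairs of one treatment, with a median of 0.929. The 81 pairs of different treatments ranged from 0.806 to 0.981, with a median of 0.928. No 2 arrays held the same values. The lowest mean correlations with the other arrays were 0.852 for SA array 100 and 0.88 for silwet array 97, both of replicate number 1.

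**Figure D1:**
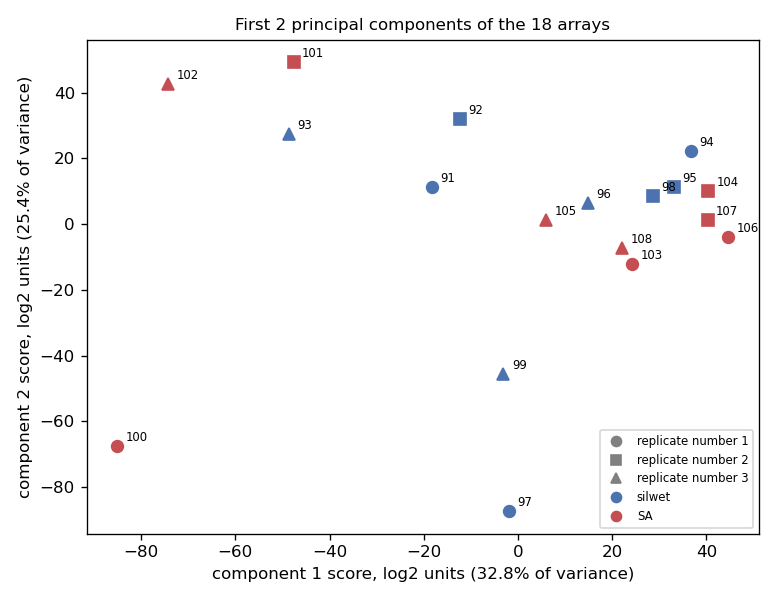
Scores of the 18 arrays on the first 2 principal components of log2 signal over the 15922 tested probe sets, in log2 units. Each point is one array with its number, the colour gives the treatment and the shape the replicate number. Component 1 held 32.8% and component 2 25.4% of the variance. SA arrays 100, 101 and 102 had scores of -85.1, -47.6 and -74.2 on component 1, and the other 6 SA arrays lay between 6.04 and 44.7. The lowest silwet arrays on it were 91, 92 and 93 with -18.2, -12.3 and -48.6, and the other 6 lay between -3.08 and 36.8.

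The first comparison asked which transcripts differed between plants given SA and plants given the surfactant alone. The highest mean difference among the named genes described here was that of AT3G28510, an AAA-type ATPase. Its log2 signal was 5.44 ± 0.998 after SA and 2.41 ± 2.38 after silwet (SD, n = 9 arrays each), a difference of 3.03 with an SE of 0.78, and all 9 SA arrays lay above the silwet median. The gene was placed first after its values were seen, so this count follows partly from that choice. The silwet values were dim and scattered, down to -2.02 on array 91 and -0.58 on array 97. Silwet arrays 94, 95 and 96 reached 4.11, 4.81 and 4.54, while the lowest SA arrays, 106 and 108, had 3.98 and 4.35. The difference was 2.48 without array 91, 2.17 without replicate number 1, 2.1 with a floor at the 20th percentile and 1.85 with array weights. Its neighbour in the same family, AT3G28540, measured 0.81 higher (SE 0.24), again with 9 of 9 SA arrays above the silwet median. GH3.3, which joins amino acids to auxin, measured 1.32 higher (SE 0.51), with 8 of 9 arrays above. None of these passed the test, and the limma adjusted p of each was 1.

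No probe set passed an adjusted p of 0.05 in limma. Of 15922 probe sets tested, 0 were called higher and 0 lower after SA, and the lowest adjusted p was 1. An unadjusted p under 0.05 was reached by 183 probe sets, 94 higher and 89 lower. That is 1.15% of the probe sets, where 5% would be expected on average if none differed and the model held. The share was 0.659% without replicate number 2 and 3.45% with array weights. An exact rank-sum test per probe set also called 0, with 188 at an unadjusted p under 0.05, but its smallest possible p of 4.11e-05 needs 14 fully separated probe sets before any can pass. With the replicate number as a block, limma called 0 and 248 had an unadjusted p under 0.05. In simulated data that kept the residuals of these arrays, with 200 of 15922 probe sets changed and 9 arrays in each group, the same test recovered a median of 61.0% of changes of 1 log2 unit and 95.5% of changes of 2 log2 units. The simulated changes were placed at random and alike on every array of a group, so these shares do not cover a change present on some arrays only.

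Because no probe set passed, the rule for the largest rises and falls named no gene. The following genes were chosen after their values were seen. They are the 12 highest and 12 lowest mean differences among the 92 probe sets with 1 gene that had an unadjusted p under 0.05 and the same sign within every replicate number. For 12 of these 24 genes both treatment means lay below the lowest array median of signal, where log2 values scatter most. On the higher side were AT3G28510 and AT3G47050 (1.34, SE 0.57), then UGT73D1, a glycosyltransferase (1.29, SE 0.61), and AT5G44570 (1.16, SE 0.43). AT5G43310 measured 1.14 higher (SE 0.36) and AT2G37750 1.12 higher (SE 0.46). Prx37, a secretory peroxidase, measured 1.07 higher (SE 0.44), AT4G00700 0.94 higher (SE 0.36), and MMP, a matrix metalloproteinase, 0.88 higher (SE 0.33). AT4G19370 and AT1G26410, the latter a berberine bridge enzyme-like oxidoreductase, had differences of 0.88 and 0.87. For AT4G19370, 5 of 9 SA arrays lay above the silwet median. The count was 6 of 9 for UGT73D1 and 7 to 9 for the other higher genes. AT4G19370 had 5.973, 7.257 and 6.998 on SA arrays 100, 101 and 102, and 4.328 to 5.485 on the other SA arrays. On silwet arrays it had 3.271 to 4.973. UGT73D1 had 5.787 to 7.407 on SA arrays 100 to 103 and 3.506 to 4.989 on the other SA arrays. On silwet arrays it had 0.2579 to 4.962.

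On the lower side, the lowest mean difference of the 12 genes was -1.02 (SE 0.45) for AT5G47330. AT1G78030 and AT3G57770 followed at -0.95 and -0.93. AT5G44380, another berberine bridge enzyme-like protein, had the smallest unadjusted p of the lower genes, with a difference of -0.86 (SE 0.24) and all 9 SA arrays below the silwet median. XTH20, which remodels xyloglucan in the cell wall, differed by -0.83 (SE 0.29), and SWEET17, a vacuolar fructose transporter, by -0.71 (SE 0.29). Differences of the remaining members were -0.85 for AT5G09570, -0.77 for AT5G57830, -0.74 for AT2G38520, -0.73 for AT3G26540, -0.64 for AT5G58660 and -0.62 for AT1G42365. Single arrays left out moved 7 of the 24 differences by over 1.5 times, to 0.84 for AT3G47050 (array 91), 0.82 for UGT73D1 (97), -0.62 for AT1G78030 and -0.47 for AT2G38520 (both 108), -0.54 for AT3G57770 (103), -0.47 for AT5G57830 (101) and -0.43 for AT3G26540 (100). Array weights moved 11 of the 24 by over 1.5 times, among them UGT73D1 to 0.20 and SWEET17 to -0.24, and turned none. In limma the adjusted p of every gene named here was 1.

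**Figure D2:**
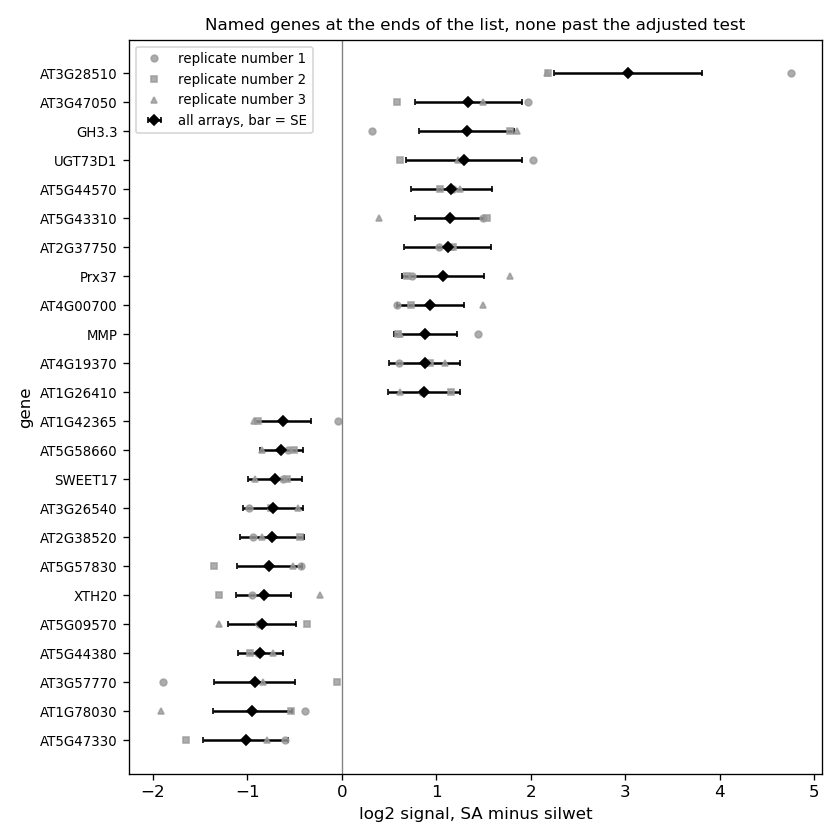
Difference in mean log2 signal, SA minus silwet, of the 24 genes at both ends of the list. Black diamonds give all 18 arrays with the SE as bar, and grey symbols give the difference within each replicate number (3 arrays against 3). The values ran from -1.02 for AT5G47330 to 3.03 for AT3G28510, and none passed the adjusted test.

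Gene lists fixed before the data were examined covered 309 genes in 16 lists, but the annotation named a probe set for 41 of them. PR1, PR2 and PR5 were not among these and have no value here. Of the SA response list, 2 genes were measured. WRKY53, a transcription factor of defence and senescence, had a difference of 0.47 (SE 0.54), and GRX480, a glutaredoxin, 0.11 (SE 0.48). Of SA synthesis and signalling, AT5G52810, which acts in pipecolic acid synthesis, had 0.27 (SE 0.34) and SAG101, a partner of EDS1, 0.15 (SE 0.19). With array weights these 4 genes turned to -0.17, -0.35, -0.17 and -0.20. Among 6 detoxification genes, UGT76B1, which glucosylates SA and isoleucic acid, had the smallest unadjusted p. Its difference was 1.98 (SE 1.04), with 7 of 9 SA arrays above the silwet median and an SD of 3.14 among SA arrays against 1.48 among silwet arrays, and array weights gave 0.91. BSMT1, a methyltransferase of SA and benzoic acid, had -0.42, GSTU25 -0.48 and UGT73B5 0.32. No member of any fixed list passed, either adjusted over all probe sets or adjusted over the list alone.

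Of the 6 fixed lists with at least 3 measured genes, 1 passed camera's test against all other probe sets. The 4 measured jasmonate and ethylene response genes had a median difference of -0.70 (camera adjusted p = 0.0165) and all 4 were lower. THI2.1, a thionin, had -0.98 (SE 0.54). The defensins PDF1.2 and PDF1.2b had -0.75 and -0.65, and JMT, which methylates jasmonic acid, -0.42. With array weights these 3 had -0.21, -0.15 and -0.97. The call was lost with an estimated correlation (adjusted p = 0.115). Within replicate numbers 1, 2 and 3 the mean difference of the list was -1.30, -0.88 and 0.07, and without replicate number 1 the adjusted p was 0.454. Leaving out single arrays 91, 97, 98, 101, 103, 104 or 106 also ended the call, with adjusted p of 0.0535, 0.152, 0.0563, 0.0625, 0.0551, 0.101 and 0.0547.

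The other 5 fixed lists did not pass. The median difference was -0.05 for detoxification (adjusted p = 0.496), 0.04 for endoplasmic reticulum chaperones and secretion (0.324), -0.10 for photosynthesis (0.361), 0.38 for auxin (0.135) and -0.18 for cold and drought (0.324). The detoxification list had a median below 0 and a mean of 0.22, with camera's direction up. In the auxin list WES1 had 0.38 and IAA29 -0.28 beside GH3.3, and array weights turned WES1, and with it the median of the list, to -0.03. AT2G34250 had 0.16 among the secretion genes, ATERDJ3B 0.16, AT1G29310 0.04 and BZIP60 -0.06. LHCB4.2 and LHCB4.1, of the light-harvesting antenna, had -0.17 and -0.09, RCA -0.10 and PSAE-1 0.05. COR15A, COR15B, COR47 and LTI30 ran from -0.25 to -0.06, and array weights turned COR15B to 0.21, COR47 to 0.25 and the median of the list to 0.09. Single measured members of smaller lists were GI of the clock (0.01), AT2G29500 of the heat shock proteins (-0.25), UGT74B1 of camalexin and indole compounds (-0.16) and AOP3 of glucosinolates (-0.50). For senescence SAG29 had 0.73 (SE 0.91) and WRKY6 0.02. The root marker PYK10 had -0.03 (SE 0.29). No gene of the lists of cysteine-rich and wall-associated receptor kinases and of flower markers had a named probe set here.

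To widen this coverage, 25 further lists were written from the genes that the annotation names, before any of their values were seen but after the fixed lists had been found thin. Of these, 24 had at least 3 measured genes, and 4 passed camera's test adjusted over the 24. The 40 measured loci recalled as induced in SA-dependent defence had a median difference of 0.23 (adjusted p = 1.49e-06), with 32 higher and 8 lower. The call was lost with an estimated correlation (p = 0.0912, adjusted p = 0.714) and under exact permutation of treatment within replicate numbers (adjusted p = 0.96). With array weights the median turned to -0.17 (adjusted p = 0.376). AT3G28510, AT3G28540, AT4G00700 and AT1G26410 had its smallest unadjusted p-values. No member passed over all probe sets, and 1 passed when adjusted over this list alone. Without arrays 97 and 100 the median was 0.04 and the adjusted p 0.142. The list's mean signal on SA arrays 100, 101 and 102 was 7.74, 8.19 and 8.16. On the other 6 SA arrays it lay between 6.51 and 7.15, and the highest silwet arrays were 91, 92 and 93 with 6.93, 7.27 and 7.49, the others lying between 6.32 and 6.93. The fixed detoxification list had 6.86, 7.41 and 7.39 on arrays 100, 101 and 102 and 6.18, 6.66 and 7.22 on arrays 91, 92 and 93, against 3.54 to 5.67 on the other 12.

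The 12 measured jasmonate genes, 4 of which also stand in the fixed jasmonate list, had a median of -0.38 (adjusted p = 0.000743) and 11 were lower. Besides THI2.1, PDF1.2 and PDF1.2b these included ORA47, a regulator of jasmonate synthesis (-0.42), and OPCL1, an enzyme of that pathway (-0.32). With an estimated correlation the p was 0.00497 and the adjusted p 0.119. Within replicate numbers 1, 2 and 3 the mean difference was -0.72, -0.56 and 0.00. Without number 1 the median was -0.31 and the adjusted p 0.21. The 26 photosynthesis genes of the nucleus had a median of -0.10 (adjusted p = 0.0206), with 23 lower, LIL3:1 at -0.27, LHCB4.2 at -0.17, LIL3:2 at -0.19 and SBPASE at -0.12. The 43 photosynthesis genes of the plastid genome had a median of 0.11 (adjusted p = 0.0435), with 30 higher, atpA at 0.59 and ndhJ at 0.32. The plastid median was -0.03 without array 97, 0.00 without replicate number 1 and -0.01 with array weights, and the mean within number 3 was -0.10. Both were lost with an estimated correlation (adjusted p = 0.714 and 0.727), and single arrays left out also ended both, among them array 97 (0.145 and 0.878). SA array 100 had the lowest mean of the fixed photosynthesis list among SA arrays, 10.8 against a median of 11.4 on the others. With the replicate block the list of plastid ribosomal protein and polymerase genes passed camera as well (median 0.18, adjusted p = 0.0377 against 0.116 without the block). With the block and an estimated correlation its camera adjusted p was 0.676.

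**Figure D3:**
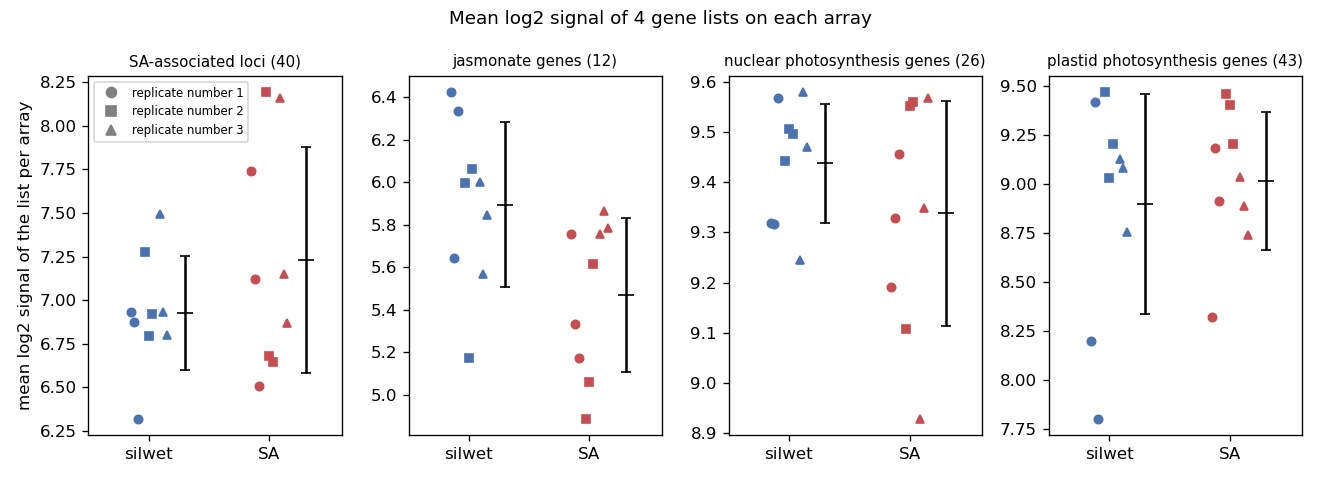
Mean log2 signal per array of the 40 SA-associated loci, 12 jasmonate genes, 26 nuclear and 43 plastid photosynthesis genes. Each point is one array, shapes give the replicate number, and black bars give the mean with the SD of 9 arrays. For the SA-associated loci the mean was 7.23 ± 0.65 after SA and 6.93 ± 0.33 after silwet, and arrays 100, 101 and 102 are the highest 3 points.

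The other 20 added lists did not pass. Among enzyme families, the median was -0.11 for 30 glycosyltransferases (adjusted p = 0.300), -0.09 for 12 glutathione transferases (0.489), -0.03 for 11 CYP71B cytochromes (0.942), -0.08 for 11 beta-glucosidases (0.581) and -0.01 for 19 serine carboxypeptidase-like proteins (0.581). SCPL45 had 0.35 (SE 0.14) and BGLU15 -0.40 (SE 0.21). SWEET sugar transporters had a median of -0.12 (0.236), with SWEET16 at -0.41. The 16 expansins and xyloglucan enzymes had -0.04 (0.942), with EXPA16 at 0.41. ATG8 autophagy proteins had 0.03 (0.149), with ATG8H at 0.52, and tetraspanins -0.01 (0.581). AGAMOUS-like factors had -0.03 (0.581), tubulins -0.07 (0.695), cell division and histone genes -0.09 (0.116) with HTB11 at -0.61, and flavonoid and lignin genes -0.26 (0.144).

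For stress and defence, 14 endoplasmic reticulum folding genes had a median of 0.11 (adjusted p = 0.0633), with DER1 at 0.24. The 34 TIR-domain resistance proteins had 0.04 (0.0633), with AT1G72890 at 0.47 (SE 0.20) and AT1G72950 at 0.39 (SE 0.18). The 17 receptor-like kinases had 0.07 (0.130), with AT1G51890 at 0.65 (-0.03 with array weights), and the 15 calmodulin-like and rapidly induced regulators 0.03 (0.480), with CML43 at 0.51. The added auxin list had 0.04 (0.465), with GH3.9 at 0.48, and the 107 cytosolic ribosomal proteins -0.01 (0.581). Of the vacuolar processing enzymes, with 2 measured genes and no test, BETA-VPE had -0.32 and GAMMA-VPE 0.00.

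The comparison was repeated within each replicate number, 3 SA arrays against 3 silwet arrays. Limma called 0 probe sets within each number, and 56, 150 and 166 had an unadjusted p under 0.05 within numbers 1, 2 and 3. The difference of AT3G28510 was 4.75, 2.18 and 2.17, and that of UGT76B1 1.74, 2.14 and 2.05. GH3.3 had 0.32, 1.78 and 1.85. PDF1.2 had -1.65, -0.58 and -0.02. Over all 15922 probe sets, 5027 had the same sign within all 3 numbers, 31.6% against 25% for independent signs. Probe sets are not independent replicates. The interaction of treatment with replicate number passed for 0 probe sets in limma, with 88 at an unadjusted p under 0.05. Without array 94 it passed for 1 probe set.

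RNA quality was compared through control probe sets at the 3' and 5' ends of 2 transcripts. The mean log2 3'/5' ratio of actin was 2.1 ± 0.51 after SA and 2.16 ± 0.53 after silwet (SD, n = 9, exact two-sided permutation p = 0.809). For GAPDH it was 0.09 ± 0.44 and 0.00 ± 0.30 (SD, n = 9, exact permutation p = 0.621). A second set of control probe sets gave differences of 0.04 for GAPDH and 0.01 for actin, with exact permutation p of 0.465 and 0.932. The mean log2 signal of the hybridisation controls was 8.30 ± 0.49 after SA and 8.48 ± 0.27 after silwet (SD, n = 9, exact permutation p = 0.35). Adjusted over these 5 tests, each p was 0.932. These tests compare treatments and not replicate numbers. The highest actin ratios were 3.42 on silwet array 91 and 3.19 on SA array 100. The highest GAPDH ratios were 0.86 on SA array 100 and 0.66 on SA array 103. All of these arrays have replicate number 1, while silwet array 94 of that number had 1.54 for actin and -0.17 for GAPDH. A difference in RNA quality between numbers was not tested.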

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

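All tests of technical explanations in this part were chosen after the result was seen, except the correlations of the components with the 3'/5' ratios and with the hybridisation controls. An array was set apart here where its gap to the next array, divided by the range of its treatment's 9 arrays, exceeded Dixon's 95% critical value. This held for 11 of 120 groups of values looked at. For values not chosen by their size, chance gives about 5%. The groups include the 24 genes at both ends of the list, which were chosen from these same arrays. An array far from the rest can help a gene to be chosen, and most of the 11 were such genes. The 11 of 120 can therefore not be set against 5%. Silwet array 91 and SA array 100 each accounted for 4 of the 11.

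SA array 100 was lowest for the fixed photosynthesis list among SA arrays (gap ratio 0.718, log2 signal 10.8 against a median of 11.4 on the others), highest for the actin 3'/5' ratio (0.501, 3.19 against 2.02), lowest for AT4G00700 (0.535, 4.54 against 6.56) and lowest for AT3G26540 (0.7, 0.87 against 3.67). Silwet array 91 was highest for the actin 3'/5' ratio among silwet arrays (0.553, 3.42 against 1.98). It was lowest for AT3G47050 (0.56, -0.87 against 3.59), for MMP (0.531, 0.79 against 3.18) and for AT4G19370 (0.643, 3.27 against 4.78). Silwet array 97 was lowest for UGT73D1 (0.721, 0.26 against 4.60) and silwet array 94 for AT1G78030 (0.501, 2.98 against 4.02). SA array 101 was lowest for AT5G57830 (0.577, 0.69 against 3.36). Without the array set apart, the difference was 0.84 for AT3G47050 (1.34 on all arrays), 0.82 for UGT73D1 (1.29), 0.63 for MMP (0.88), 0.72 for AT4G19370 (0.88), -0.47 for AT5G57830 (-0.77) and -0.43 for AT3G26540 (-0.73). For AT4G00700 and AT1G78030 it was larger without that array, 1.19 (0.94) and -1.07 (-0.95), while AT1G78030 had -0.62 without SA array 108.

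The arrays stood apart from each other more than the treatments did. Across all 18 arrays the mean of the 4 log2 3'/5' ratios correlated with component 2 (Pearson r = -0.558, permutation p = 0.016, adjusted over 6 relations p = 0.024, Spearman rho = -0.387 with permutation p = 0.11, r = -0.545 without the 2 farthest arrays). The hybridisation controls also went with component 2 (r = 0.564, permutation p = 0.016, adjusted p = 0.024, rho = 0.657 with permutation p = 0.004, r = 0.615 without 2 arrays). The log2 median signal went with component 1 (r = 0.675, permutation p = 0.0024, adjusted p = 0.014, rho = 0.68 with permutation p = 0.0021, r = 0.612 without 2 arrays), and with component 2 (r = 0.629, permutation p = 0.0059, adjusted p = 0.018, rho = 0.362 with permutation p = 0.14, r = 0.199 without 2 arrays). The components were computed from the same signals, without bringing the arrays to one median. The median and the components are therefore not independent measures. With component 1 the 3'/5' ratios had r = -0.284 (permutation p = 0.25, adjusted p = 0.3). The hybridisation controls had r = 0.0832 with it (permutation p = 0.74, adjusted p = 0.74). RNA quality and the brightness of the hybridisation controls may therefore account for part of component 2. The distribution of signal on an array may account for part of either component, which its correlations cannot decide. Since RNA quality and the distribution can follow from biology as well, a cause was not singled out. A biological explanation such as the time of harvest was not tested, because the labels give none.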

How the results depend on the processing

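The residual components, the rank-sum test, the test of spread, the permutation of list means and the omission of arrays 97 and 100 were chosen after the data were seen. The counts of 0 higher and 0 lower probe sets held under every alternative chosen beforehand, the replicate block included. The rank-sum test called 0 as well. The test of spread, which compares absolute deviations from the treatment median and not levels, called 0 probe sets. Components of the residuals as covariates gave 3 higher with 2 components, 6 with 3, 33 higher and 15 lower with 4, 44 higher and 28 lower with 5, and 0 with 1. These counts were not read as evidence of an SA effect. With 2, 3, 4 and 5 components, 20 splits of the arrays within replicate numbers gave medians of 553.5, 1061, 1672.5 and 2336 calls. The splits balance the numbers only, and not the differences among arrays seen on component 1. They therefore cannot decide what the counts mean. The interaction passed for 0 to 1 probe sets with arrays or numbers left out.

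The fixed lists called, 1 as reported, were 0 to 2 with arrays or numbers left out. They were 0 with array weights, with an estimated correlation, with permutation, and with the 50% filter, which left too few jasmonate genes to test. The added lists called, 4 as reported, were 2 to 9 with arrays or numbers left out, 2 without a filter, 1 without arrays 97 and 100, and 0 with an estimated correlation or permutation. The estimated correlation and permutation change only the p-value and cannot move a median. The medians were -0.701 (jasmonate and ethylene), -0.384 (added jasmonate), 0.232 (SA-associated), -0.102 (nuclear photosynthesis) and 0.113 (plastid photosynthesis), and under these 2 settings none passed. With arrays or numbers left out these medians ranged from -0.968 to -0.336, -0.562 to -0.265, 0.0753 to 0.345, -0.137 to -0.0544 and -0.0297 to 0.232. Array weights gave -0.451 and -0.187 for the jasmonate lists, no longer past the threshold. They gave -0.171 for the SA-associated loci, -0.00521 for plastid and -0.0157 for nuclear photosynthesis, all 3 with camera's direction turned and none past the threshold. Without a filter, nuclear (-0.102) and plastid (0.113) photosynthesis genes did not pass. The plastid genes also missed after quantile normalization (0.118). Without arrays 97 and 100 the SA-associated loci (0.0431), nuclear (-0.0772) and plastid (0.0302) photosynthesis genes did not pass.

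Several lists that did not pass as reported did so elsewhere, always at camera's preset correlation. These were plastid expression with the block (0.177), TIR-domain proteins after quantile normalization (0.0529), endoplasmic reticulum folding (0.108) and flavonoid and lignin genes (-0.279) with the 50% filter, and, with array weights, ATG8 (0.152), cytosolic ribosomal proteins (0.0812) and receptor-like kinases, which turned to -0.163. Others passed in some of the repeats that left out arrays or numbers, and the medians in all of these repeats ranged from 0.206 to 0.546 (fixed auxin), -0.318 to -0.0492 (cold and drought), -0.144 to 0.0589 (beta-glucosidases), -0.0374 to 0.138 (ATG8), 0.0171 to 0.271 (plastid expression), 0.0252 to 0.155 (endoplasmic reticulum folding), -0.135 to 0.18 (calmodulin-like), -0.424 to -0.0617 (flavonoid and lignin), -0.155 to -0.0482 (cell division), -0.103 to 0.136 (added auxin), -0.0349 to 0.0333 (cytosolic ribosomal proteins), -0.0194 to 0.109 (TIR-domain) and -0.0129 to 0.163 (receptor-like kinases). The cause of these changes was not tested. Of 5818 recomputed values 5683 stayed on their side of the threshold or near their count. Most of the values belong to single named genes, whose limma adjusted p was 0.999 or more throughout, so they could hardly change. The plastid photosynthesis list changed in 14 of its 33 alternatives and the fixed jasmonate list in 11 of 32. Among the 5683, 209 that passed in neither setting took the other sign (for lists, camera's other direction), which was not counted as a change. This rule was made after their number was seen. No named gene and no RNA quality measure passed in the alternatives computed for them. Array weights moved 96 of 140 named genes by over 1.5 times or turned them, and 28 of these turned. The share of probe sets at an unadjusted p under 0.05 ranged from 0.659% to 3.45%, the latter with array weights. The residual components, rank-sum test and test of spread were not looked up for single named genes. The median over a gene's probe sets moved no median of a list, so it tested little.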

Other observations

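The tests in this part were chosen after the results were seen, except the one on quantile normalization and the one that leaves out single arrays from the jasmonate list. The per-array values of UGT76B1 and the SA-associated loci differed widely among SA arrays, with the SA-associated loci highest on SA arrays 100, 101 and 102 and, less far apart, on silwet arrays 91, 92 and 93. No label states what separates these arrays, and they were not compared as a group. The SD among SA arrays was larger than among silwet arrays for 18 of 30 lists, and 61.4% of probe sets had the larger variance in SA, with a median log2 variance ratio of 0.327. The SD of the SA-associated loci was 0.648 after SA and 0.325 after silwet (exact permutation of absolute deviations, p = 0.0644, adjusted over the 30 lists p = 0.467). Expansins and xyloglucan enzymes had SDs of 0.383 and 0.0961 (exact permutation p = 0.0225, adjusted p = 0.467), tubulins 0.425 and 0.172 (p = 0.0473 by exact permutation, adjusted p = 0.467), and beta-glucosidases went the other way with 0.089 and 0.328 (exact permutation p = 0.0385, adjusted p = 0.467). Of 100 splits that keep replicate numbers balanced, 43 gave as large a median variance ratio in either direction, with a highest other of 1.14, so a larger spread after SA is not separated from chance.

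Small p-values were few in the comparison of SA with silwet. Quantile normalization changes only the distribution of signal between arrays and keeps the authors' other processing steps, which were not tested. It left 1.26% of probe sets at an unadjusted p under 0.05 in limma, so the scaling between arrays is not the whole cause. Array weights gave 3.45%. A candidate explanation is a large difference among arrays of one treatment that the labels do not give, and the first 2 components held 59.9% of the variance left after treatment. Such a difference would enlarge the spread within treatments, and with it the error for the genes it affects. Whether it accounts for the few small p-values was not tested further. A real count of 0 is reached by every split, so the 100 splits of the 18 arrays and the 100 splits balanced over replicate numbers decide nothing about it. The highest other counts were 1 and 0. In the balanced splits the share of unadjusted p under 0.05 reached 16.2%, against 1.15% in the real split. Of them 67 reached the real share, and their median was 1.46%.

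The interaction gave 0 calls, which each of the 100 balanced splits must reach, so these decide nothing either. The highest other was 90. Within replicate numbers 1, 2 and 3, the 10 splits of 6 arrays are too few for a share under 0.05; the real splits gave 0 calls and the highest others 0, 1 and 6. The 186 probe sets that differed between replicate numbers were reached by 3 of 100 shuffles of the numbers, the real one included, with 1780 as the highest other. This share is under 0.05, while some shuffles called several times more. The shuffles ignore differences among arrays that the labels do not give, so chance is not firmly excluded.

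The shifts of SA-associated loci and jasmonate genes by list were the pattern nearest to a response to SA. As many fixed lists as the 1 called were called by 47 of 100 balanced splits, with 2 as the highest other, and as many added lists as the 4 called by 76 of 100, with 12 as the highest other, so chance is not excluded for these counts. The SA-associated list reached a minus log10 camera p of 7.21, and 17 of the 100 balanced splits gave as small a p, with 14.9 as the highest other, so chance is not excluded for this list either. These splits balance the replicate numbers and no other difference among arrays, so their shares are only a rough measure of chance. Members of the SA-associated list vary together between arrays of one treatment, which may account for its small camera p, since with an estimated correlation the p was 0.0912. A single array does not carry the shift of the added jasmonate list, because the highest adjusted p with 1 array left out was 0.0177, without array 104, at camera's preset correlation. The call itself was lost with an estimated correlation (adjusted p = 0.119). Without replicate number 1 its adjusted p was 0.21, while the median stayed at -0.308 against -0.384. The mean signal of the added jasmonate list was 5.75, 4.89 and 5.75 on SA arrays 100, 101 and 102, where the SA-associated loci were highest. On the other SA arrays it lay between 5.06 and 5.87, a range that overlaps these values. Antagonism between SA and jasmonate was not tested, and the values given here do not decide it.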
